A study of Mus musculus with 127 samples.

How the data were processed

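RNA was measured in 127 single cells from mouse cultures, 113 striatal neurons and 14 astrocytes. Each neuron had been recorded electrically in the whole-cell mode and its content then drawn into the pipette, a procedure called Patch-seq. Per the labels, full-length cDNA was made with SMARTer chemistry and libraries with Nextera XT, and no molecular identifiers were named. The series text counts 117 neurons, and the 113 held here are all that the deposited table and labels give. The electrical recordings were not analysed here.

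The deposited table holds raw counts of reads per Ensembl gene, 1 column per cell, with no normalization. The processing notes of the submitters name FastQC, Trimmomatic 0.36, STAR 2.5 and HTSeq 0.9.1 and the builds GRCm38 and mm10. The trimming and alignment settings, the annotation release and the strand setting of the counting are not given in the sources used here. The values were checked to be whole numbers with totals that differed between cells. The table has 53465 genes, of which 53274 were matched by identifier to a symbol and 191 were not. Gene positions on GRCm38 were taken from GENCODE release M21. The human transgene and the fluorescent tag are not in the table, so the endogenous mouse Htt gene could not be used to check which construct a cell carried.

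Total counts per cell ran from 999700 to 9263305, with a median of 4440040, and a cell had a count in 6433 to 15455 genes, with a median of 11911. A minimum of 50000 counts and 1000 genes per cell removed no cell. No 2 cells had identical counts, and the highest Pearson r of log2(count + 1) between 2 cells was 0.733, against a median of 0.537. PCR reads without molecular identifiers are not independent molecules, so all confidence intervals given for counts and shares cover counting error only.

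Each deposited sample is 1 cell, and the labels name no animal or culture. The only labelled level above the cell is the batch, and each of the 4 groups of neurons with a transgene is present in batches 1, 2 and 3. Raw counts of the cells of a group within a batch were therefore summed, which gave 12 sums with 8617702 to 75755859 counts, and the batch served as the replicate (n = 3 per group). The p-values measure only how differences between groups vary from batch to batch, pooled over the 4 groups. This spread includes the sampling of cells, with 3 to 15 cells per sum. Spread between animals cannot be given, because the number of animals behind a batch is unknown. Whether the batch pairs the sums was checked on the deviation of each sum from the mean of its group. The Pearson r across genes between sums of a shared batch was 0.155 to 0.229 in batch 1, 0.062 to 0.133 in batch 2 and 0.252 to 0.325 in batch 3, and it reached at most 0.095 between sums of different batches. Genes are not independent replicates, so these r values carry no p.

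Genes were kept when edgeR's filterByExpr passed them on the 12 sums and when at least 20% of the 104 cells of the 4 groups had a count, which left 15091 genes. The sums were normalized by TMM and fitted with edgeR 4.0.16 by a robust quasi-likelihood model with terms for group and batch, which leaves 6 residual degrees of freedom. The common biological coefficient of variation was 0.928. The contrasts were 97Q against 25Q under vehicle, RGFP109 against vehicle within 97Q, RGFP109 against vehicle within 25Q, 97Q with RGFP109 against 25Q with vehicle, and the difference between the drug effects in 97Q and in 25Q, called the interaction. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes (log2FC) come from this fit. Their standard errors (SE) were derived as the absolute log2FC over the square root of the test's F statistic. Counts scaled to library size (CPM) are given as the mean over the 3 sums of a group, with the SD. Values by batch are not from the fit. They are differences within a batch of log2(CPM + 1), which shrinks differences of genes with low counts. A value of the fit can therefore lie outside its 3 values by batch.

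Lists of genes for 39 pathways, complexes and cell types were written down beforehand, and the 37 with at least 5 tested genes were tested with camera from limma 3.58.1 on the same fit, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, the fry test, and the percentile of each list's median among 10000 random lists matched on mean expression. Camera compares a list with the other genes, whereas fry tests whether a list's own genes moved on balance to 1 side. Members of a list were also adjusted over the list alone. For a gene in several lists, the smallest of these adjusted values is given. They were not adjusted further for the number of lists or contrasts. A list that rose or fell is one past the threshold of camera with the preset correlation.

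Named genes were taken by a fixed rule. For each of the first 3 contrasts the rule takes up to 10 genes per direction past the threshold that had the same sign in all 3 batches and a count in at least 50% of the cells of a group, then fills each direction up to 5 by the smallest p. It always adds Htt, Hdac1, Hdac3, Gad1, Gad2, Slc32a1, Bdnf and Ppp1r1b, and the 4 members with the smallest p of each list past its threshold. For the remaining contrasts it takes the 5 genes with the smallest p per direction. Predicted gene models were not named. Genes named outside this rule are marked where they occur. Values of a few genes that the rule takes are not reported here.

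Empty vector neurons and astrocytes are in batch 3 alone, so each is 1 sum without replicates and no p-value was computed for them. Their CPM carry exact Poisson intervals, shares of cells carry exact Clopper-Pearson intervals, and log2 ratios use a prior of 1 CPM. The rule for empty vector neurons names the 5 highest and 5 lowest ratios among genes with a count in at least 50% of the cells of both groups. Values per group and batch, such as the summed CPM of a list, were compared by an exact permutation test within batches, whose smallest possible p with 3 batches is 0.25.

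The covariance across genes of the log2FC of 97Q against 25Q with that of RGFP109 against vehicle in 97Q was computed as well. Both contrasts hold the 97Q vehicle cells, with opposite sign. It was therefore also computed with the 97Q vehicle cells of each batch divided at random between the contrasts, in 100 draws. For comparison, the labels of 25Q vehicle, 97Q vehicle and 97Q RGFP109 cells were shuffled within each batch, in 100 draws, to give shuffled groups. Any true difference between the groups stays in the shuffled cells and can widen their range.

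The pipeline was tested on simulated data with the design of 97Q against 25Q, in which 200 of 15091 genes were changed. The changed genes were drawn only from genes with a mean log2 CPM above 4, so their calls do not cover genes with lower counts. The quasi-likelihood test called 0 of 67 genes changed 2-fold, 0 of 67 changed 4-fold, 36 of 66 changed 16-fold and 0 of 14891 unchanged genes. DESeq2 called 3, 19 and 60 of these and 186 of the 14891 unchanged genes. Camera called the simulated lowered list of 30 genes and 0 of 36 unchanged lists, with the preset and with the estimated correlation. Genes were drawn independently of each other, so these calls do not cover lists whose genes vary together. The simulated covariance of unchanged groups was -0.4338 with shared sums and 0.007 with separate sums, and with genes changed and changed back it was -0.0787 with separate sums against a true value of -0.0851.

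The grouping, filters, lists, tests, named gene rule and first set of alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors in place of TMM, the DESeq2 1.42.0 Wald test, limma on mean log2(CPM + 1) over cells, filterByExpr alone, no gene filter, no cell filter, a minimum of 3000 genes per cell, cells thinned to 50000 counts, no batch term, the astrocyte list as a covariate, each batch left out in turn, and only the 2 groups compared. Chosen after seeing the data were cells thinned to 900000 counts, leaving out each cell in turn for Gad1 and Gad2, and leaving out the 11 neurons in which the astrocyte and microglia lists together took more counts than the pan-neuronal list. Scripts ran under R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.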

Results

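Striatal neurons from newborn C57BL/6 mice were grown on small islands of astrocytes and infected with lentiviruses carrying human huntingtin exon 1 fused to a fluorescent protein. Its polyglutamine tract held 25 glutamines (25Q) or, expanded, 97 (97Q). The neurons received vehicle or RGFP109, an inhibitor of the histone deacetylases HDAC1 and HDAC3, at 100 nM. After recording, RNA was read from 29 neurons of 25Q vehicle, 26 of 97Q vehicle, 23 of 25Q RGFP109 and 26 of 97Q RGFP109, each group spread over batches 1, 2 and 3. Batch 3 also held 9 neurons with an empty vector and 14 astrocytes. The median count per cell was 3821912 in 25Q vehicle, 3907017 in 97Q vehicle, 3785524 in 25Q RGFP109 and 4511459 in 97Q RGFP109 neurons. It was 5150586 in empty vector neurons and 7441964 in astrocytes. Batch 2 was the smallest, with 15 neurons and a median of 8877 genes with a count per neuron, against 12436 in batch 1 and 11844 in batch 3. The 50 most abundant genes of a neuron took a median of 21.5% of its counts in batch 2, against 15.1% in batch 1 and 16.2% in batch 3.

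The comparison of 97Q with 25Q under vehicle asks what the expanded tract changed in transcription, in a series about inhibitory GABA signalling. Gad1 and Gad2, which encode the enzymes that make GABA, were lower in 97Q neurons in all 3 batches. Gad1 (ENSMUSG00000070880, GRCm38 chromosome 2, 70553072 to 70602014, plus strand) had a mean of 532 ± 475 CPM in 97Q and 1739 ± 1212 CPM in 25Q (SD, n = 3). Its log2FC was -1.83 (SE 0.245), with -1.69, -2.31 and -1.53 in batches 1, 2 and 3. Gad2 (ENSMUSG00000026787, chromosome 2, 22622205 to 22693874, plus strand) had 490 ± 85.8 CPM in 97Q and 1304 ± 283 CPM in 25Q (SD, n = 3). Its log2FC was -1.42 (SE 0.239), with -1.07, -1.73 and -1.40 by batch. Abat, the transaminase that degrades GABA, had a log2FC of -0.77 (SE 0.241). Slc32a1, the vesicular GABA transporter, had a log2FC of -0.47 (SE 0.993) at 16.3 CPM in 25Q.

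As a group, genes of GABA synthesis, packaging and uptake fell, with 9 of 12 lower and a median log2FC of -0.74 (-0.42, -1.22 and -0.49 in batches 1, 2 and 3). Camera with Benjamini-Hochberg adjustment gave an adjusted p = 0.000644 (adjusted p = 0.156 with an estimated correlation). Of the 12 members, 4 were lower past the threshold when adjusted over the list alone and 0 when adjusted over all genes. Over the list alone, edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 3.5e-04 for Gad1, 0.00102 for Gad2 and 0.0304 for Abat, which were among them. Over all genes the same test with Benjamini-Hochberg adjustment gave 0.445 for Gad1 and 0.969 for Gad2. Without the batch term the value of Gad1 adjusted over the list alone was 0.129 by the same test, at a log2FC of -1.71. Abat no longer passed when any 1 of the 3 batches was left out. Over 16 alternative settings the adjusted p over the list alone of edgeR's test, or of DESeq2 or limma, ran up to 0.652 for Abat.

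In single cells, the median of Gad1 was 650 CPM in 97Q and 1415 CPM in 25Q neurons, and that of Gad2 559 and 943 CPM. At least 100 CPM of Gad2 were found in 25 of 26 97Q neurons (96.2%, exact Clopper-Pearson 95% interval 80.4 to 99.9%) and in 29 of 29 25Q neurons (88.1 to 100%). For Gad1 these were 22 of 26 (84.6%, 65.1 to 95.6%) and 28 of 29 (96.6%, 82.2 to 99.9%). The highest value among the 14 astrocytes was 2.45 CPM for Gad1 and 0.816 CPM for Gad2.

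**Figure D1:**
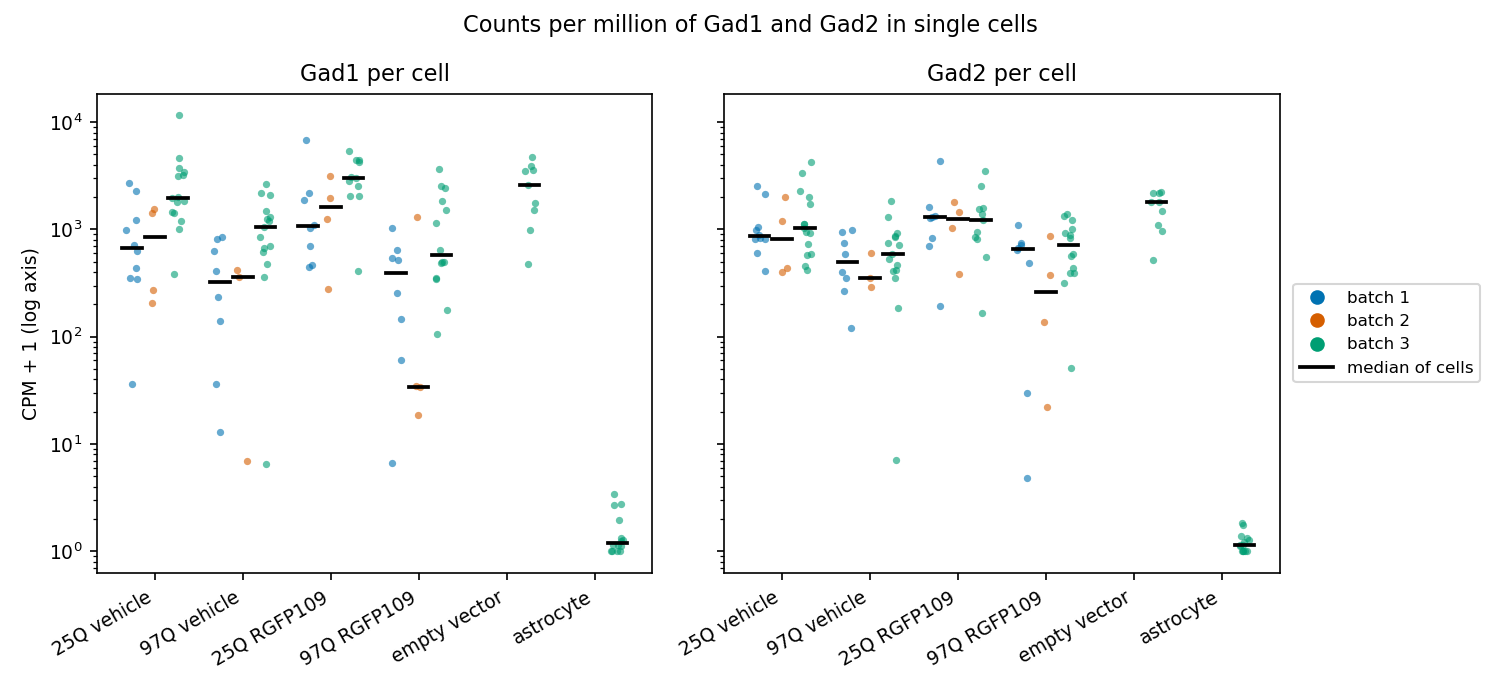
Gad1 and Gad2 in single cells, as CPM + 1 on a log axis, by group and batch, with 1 point per cell. A black bar marks the median over the cells of a group within each batch. Over all cells of a group, the median of Gad1 was 1415 CPM in 25Q and 650 CPM in 97Q vehicle neurons. It was 2055 and 495 CPM under RGFP109 and 2606 CPM in empty vector neurons, and no astrocyte had more than 2.45 CPM.

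Genes that mark striatal projection neurons fell in 97Q, with 29 of 32 lower and a median log2FC of -1.52 (-0.91, -2.53 and -1.01 by batch). The striatal list had a Benjamini-Hochberg adjusted p = 3.32e-10 by camera (adjusted p = 0.195 with an estimated correlation). Among them, Pde1b, a calcium-dependent phosphodiesterase, had a log2FC of -2.94 (SE 0.656), from 106 ± 30.7 to 14.5 ± 2.63 CPM (SD, n = 3). Gng7, a G protein subunit of striatal dopamine signalling, had -2.55, the potassium channel partner Kcnip2 -2.53 and the striatal tyrosine phosphatase Ptpn5 -1.52. Ppp1r1b, an integrator of dopamine signals, had -2.73 with an SE of 1.55. When adjusted over the list alone, 1 member, Pde1b, was lower (Benjamini-Hochberg adjusted p = 0.0438 by edgeR's quasi-likelihood test), against 0 over all genes. It no longer passed without batch 1, without batch 3 or without the 11 neurons rich in glial markers (adjusted p up to 0.238 over 16 settings). Genes of dopamine and cAMP signalling fell with 27 of 43 lower (median log2FC -0.61). The dopamine and cAMP list had a Benjamini-Hochberg adjusted p = 0.00103 by camera (adjusted p = 0.195 with an estimated correlation). Rgs2 had a log2FC of -1.64 and Akap5 one of -1.63.

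Several lists of synapse genes fell as well, but not those of synaptic vesicle release (median log2FC -0.17, Benjamini-Hochberg adjusted p = 0.067 by camera) and vesicle endocytosis (19 of 27 higher, median 0.24, adjusted p = 0.612). Glutamate receptor and postsynaptic genes had 32 of 40 lower and a median log2FC of -0.75 (-0.52, -0.96 and -0.65 by batch). The glutamate receptor list had a Benjamini-Hochberg adjusted p = 1.73e-06 by camera (adjusted p = 0.156 with an estimated correlation). The AMPA receptor subunit Gria2 stood at -1.11, the metabotropic receptor Grm5 at -1.91, the kinase Camk2a at -1.45 and the scaffold Homer1 at -1.44. GABA receptor genes had 20 of 27 lower and a median of -0.41 (-0.18, -1.09 and 0 by batch, and 0.035 without batch 2), including Gabra2 at -1.04, Gabra4 at -1.33 and Hap1 at -1.52. Synaptic adhesion genes had 25 of 36 lower and a median of -0.46 (-0.21, -0.82 and -0.15 by batch), including Cntnap2 at -1.29, Nrxn3 at -1.50 and Cadm1 at -0.98. For both of these lists camera gave a Benjamini-Hochberg adjusted p = 0.00768 (adjusted p = 0.217 and adjusted p = 0.230 with an estimated correlation). Calcium channel and calcium handling genes had 32 of 48 lower and a median of -0.66. The calcium list had a Benjamini-Hochberg adjusted p = 0.000927 by camera (adjusted p = 0.195 with an estimated correlation). The calcium pumps Atp2b2 and Atp2a2 had -2.01 and -1.10, and the calcium sensor Vsnl1 -1.18. Sodium and potassium channel genes had 32 of 48 lower and a median of -0.48. Their list had a Benjamini-Hochberg adjusted p = 0.0216 by camera (adjusted p = 0.217 with an estimated correlation), and its member Kcnn3 stood at -2.37.

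Immediate early genes fell with 19 of 23 lower and a median log2FC of -0.97. The immediate early list had a Benjamini-Hochberg adjusted p = 0.00155 by camera (adjusted p = 0.195 with an estimated correlation). Junb stood at -0.69 and Atf3 at -3.59, while Arc stood at 2.68 (SE 1.46) with fewer than 4 CPM in both groups. Neurotrophin signalling genes had 13 of 17 lower and a median of -0.67. The neurotrophin list had a Benjamini-Hochberg adjusted p = 0.0109 by camera (adjusted p = 0.195 with an estimated correlation). The receptors Ntrk2, Ntrk3 and Sort1 had -1.10, -1.66 and -1.89. Bdnf had -1.57 with an SE of 3.41. All 7 tested mitochondrially encoded genes were lower, with a median of -0.37. The mitochondrial list had a Benjamini-Hochberg adjusted p = 0.0379 by camera (adjusted p = 0.548 with an estimated correlation). In it mt-Nd1 stood at -0.40 and mt-Nd2 at -0.51.

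The lists that rose in 97Q held genes of the proteasome, interferon and innate immunity, proliferation, cholesterol synthesis and oxidative stress, each tested by camera. Proteasome genes had 42 of 46 higher and a median log2FC of 0.48 (0.41, 0.90 and 0.34 by batch). The proteasome list had a Benjamini-Hochberg adjusted p = 2.58e-07 by camera (adjusted p = 0.162 with an estimated correlation). The core subunits Psma1 and Psmb7 had 0.76 and 0.79, and the regulatory subunits Psmd7 and Psmc6 0.97 and 0.73. Interferon and innate immune genes had 23 of 26 higher and a median of 1.29 (0.97, 0.94 and 1.19 by batch). The interferon list had a Benjamini-Hochberg adjusted p = 0.000161 by camera (adjusted p = 0.217 with an estimated correlation). Its member Irf9, a transcription factor of the interferon response, had 47.8 ± 32.4 CPM in 25Q and 157 ± 110 CPM in 97Q (log2FC 1.79, SE 0.478). Isg15 at 3.91 and the inducible proteasome subunits Psmb8 at 3.15 and Psmb9 at 5.77 stood at 11 to 13 CPM in 97Q. Cholesterol synthesis genes had 19 of 25 higher and a median of 0.70 (0.71, -0.09 and 0.86 by batch). The cholesterol list had a Benjamini-Hochberg adjusted p = 0.000927 by camera (adjusted p = 0.460 with an estimated correlation). The regulator Srebf2 stood at 1.31 and the enzymes Sqle at 1.34 and Mvk at 3.17. Proliferation markers had 11 of 12 higher and a median of 2.47 (camera, Benjamini-Hochberg adjusted p = 0.000844, and adjusted p = 0.195 with an estimated correlation), at low counts. Rrm2 had 12.3 CPM in 97Q and 0.968 CPM in 25Q, with 62.3% of the 97Q counts in 1 cell. Oxidative stress genes had 23 of 30 higher and a median of 0.44. The oxidative stress list had a Benjamini-Hochberg adjusted p = 0.00505 by camera (adjusted p = 0.301 with an estimated correlation). Gclm stood at 1.51 and Park7 at 0.56.

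Lists of markers for cell types other than striatal projection neurons did not pass in this contrast. Pan-neuronal markers had 12 of 18 higher and a median log2FC of 0.45 (0.06, 0.61 and -0.04 by batch). Astrocyte markers had 11 of 22 higher and a median of 0.13 (-0.05, 1.43 and -0.47 by batch). Microglia markers had 2 of 7 higher and a median of -0.86, and oligodendrocyte markers 6 of 8 higher and a median of 0.64 (0.23, 2.19 and -0.10 by batch; camera, Benjamini-Hochberg adjusted p = 0.316). Endothelial and mural markers held too few tested genes for camera. They took 2357, 289 and 280 CPM of the 97Q sums of batches 1, 2 and 3, against 255, 182 and 115 CPM in 25Q, with up to 9370 CPM in a single 97Q cell of batch 1. Striatal interneuron markers had 5 of 8 lower and a median of -2.23 (camera, Benjamini-Hochberg adjusted p = 0.11). Their member Kit, chosen after its values were seen, had 3 counts in 97Q and 10138 in 25Q, of which 90.4% came from 1 cell. It was lower when adjusted over the list alone (adjusted p = 0.0113 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It no longer passed without batch 2 or without batch 3 (adjusted p up to 0.112 over 15 settings).

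By single genes, 0 of 15091 passed in edgeR's quasi-likelihood test, with 597 at an unadjusted p under 0.05 (226 higher, 371 lower). This is fewer than a share of 0.05 of the genes tested, the number that chance alone would give at this limit. In simulated data 492 of 14891 unchanged genes (3.3%) lay under it by the same test. The edgeR counts at an unadjusted p under 0.05 in the other contrasts below are under that share as well. DESeq2 called 213 genes (46 higher, 167 lower) and limma 0, with 1045 at an unadjusted p under 0.05. Among the genes with the smallest p outside the lists were the transcription factor Tef at a log2FC of -2.36 (SE 0.413), Kctd12, a partner of the GABA-B receptor, at -2.55 (SE 0.490) and the imprinted gene Nnat at -1.75 (SE 0.337). On the higher side were the AMP-activated kinase subunit Prkaa1 at 1.43 (SE 0.354), Efr3a at 1.61 (SE 0.427), the Polycomb gene Bmi1 at 2.08 (SE 0.566) and the ubiquitin-conjugating enzyme Ube2e3 at 1.26 (SE 0.343). Htt had 0.60 (SE 0.621), Hdac1 1.52 (SE 0.875) and Hdac3 0.15 (SE 0.284). Of the 136 genes chosen for naming across all contrasts, 47 share exon sequence with another annotated gene, among them Tef, Kctd12, Nnat, Irf9 and Gria2. The strand setting of the counting is not given, so part of their counts could not be assigned with certainty.

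Of the 37 lists, 16 passed (5 higher, 11 lower) with the preset correlation, 0 with an estimated correlation and 0 by fry. Without batch 2, calls were lost for GABA receptors (median 0.035), immediate early, neurotrophin, oxidative stress, synaptic adhesion and mitochondrially encoded genes (camera, Benjamini-Hochberg adjusted p of 0.276, 0.197, 0.145, 0.197, 0.375 and 0.321). Without batch 1 they were lost for mitochondrially encoded and sodium and potassium channel genes (0.142 and 0.117), and without batch 3 for cholesterol, neurotrophin and sodium and potassium channel genes (0.0985, 0.103 and 0.0509). Proliferation markers no longer passed without the 11 neurons rich in glial markers (0.0671) or with cells thinned to 900000 counts (0.528), and mitochondrially encoded genes without the batch term (0.0655). With the astrocyte list as a covariate, 13 of the 16 lists kept their call, and sodium and potassium channel, mitochondrially encoded and synaptic adhesion genes did not (0.0518, 0.0601 and 0.051).

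**Figure D2:**
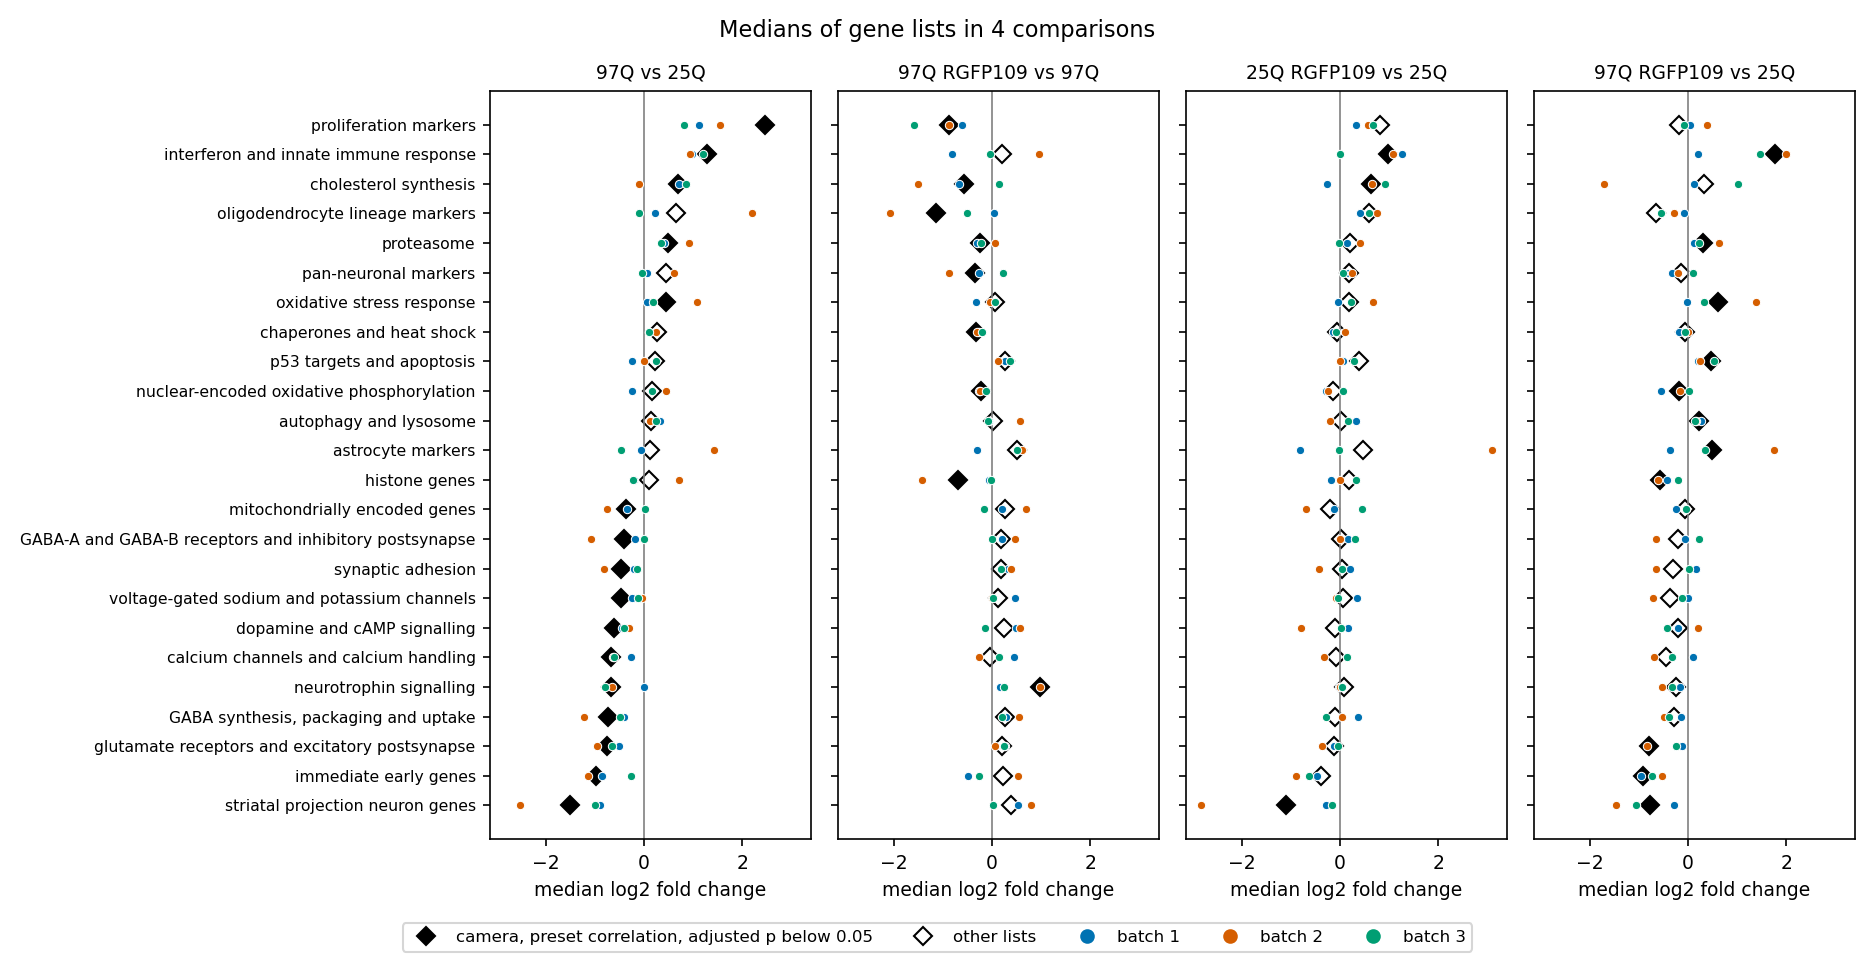
Median log2FC of 24 gene lists in the 4 comparisons of neuron groups. Diamonds mark medians of the fit, black where camera with the preset correlation gave an adjusted p below 0.05 and white elsewhere. Coloured dots mark medians within batches 1, 2 and 3 of the log2 ratio of CPM + 1. Striatal projection neuron genes stood at -1.52 in 97Q against 25Q, -1.10 in 25Q RGFP109 against 25Q and -0.77 in 97Q RGFP109 against 25Q.

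The comparison of RGFP109 with vehicle in 97Q neurons asks which transcripts the inhibitor moved in cells with the expanded tract. Gad1 had 602 ± 425 CPM with RGFP109 and 532 ± 475 CPM with vehicle (SD, n = 3), a log2FC of 0.30 (SE 0.238). Gad2 had 544 ± 174 and 490 ± 85.8 CPM, a log2FC of 0.13 (SE 0.234). The value of Gad1 depended on 97Q RGFP109 cell 10. The mean over batches of the log2 ratio of CPM + 1 was 0.20 with this cell and -0.91 without it. Known response genes of histone deacetylase inhibitors had 8 of 17 higher, with a median log2FC of -0.20 and a mean of 0.06 (camera, Benjamini-Hochberg adjusted p = 0.830). Hdac1 had -0.56 (SE 0.845), Hdac3 0.56 (SE 0.285), Htt 0.84 (SE 0.624), Bdnf 4.25 (SE 4.21), Slc32a1 0.21 (SE 0.989) and Ppp1r1b -0.17 (SE 1.63).

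Cholesterol synthesis genes fell with RGFP109 in 97Q, with 22 of 25 lower and a median log2FC of -0.57 (-0.68, -1.51 and 0.14 by batch). The cholesterol list had a Benjamini-Hochberg adjusted p = 0.000897 by camera (adjusted p = 0.538 with an estimated correlation). Among them, the synthase Hmgcs1 had -1.13, the regulator Srebf2 -1.20, Sqle -1.01 and Nsdhl -1.11. Nuclear-encoded genes of oxidative phosphorylation fell with 59 of 80 lower and a median of -0.22 (-0.26, -0.26 and -0.12 by batch). The oxidative phosphorylation list had a Benjamini-Hochberg adjusted p = 0.00568 by camera (adjusted p = 0.538 with an estimated correlation). Atp5s stood at -1.27 and the complex I subunits Ndufs1 at -0.77 and Ndufs7 at -0.92. Chaperone genes had 31 of 41 lower and a median of -0.32, including Tcp1 at -0.77 and Hsp90ab1 at -0.38. Proteasome genes had 29 of 46 lower and a median of -0.24, including Psmg2 at -1.10 and Psmb10 at -2.38. Both had a Benjamini-Hochberg adjusted p = 0.0465 by camera (adjusted p = 0.488 and adjusted p = 0.538 with an estimated correlation).

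Histone genes fell with 18 of 22 lower and a median log2FC of -0.70 (-0.06, -1.43 and -0.02 by batch), led by the replacement histone gene H3f3b, from 662 ± 28.5 to 358 ± 175 CPM (log2FC -1.03, SE 0.285). Pan-neuronal markers fell with 15 of 18 lower and a median of -0.36 (-0.27, -0.87 and 0.22 by batch), including Tubb3 at -1.79, Stmn3 at -1.08 and Stmn2 at -0.45. For both lists camera gave a Benjamini-Hochberg adjusted p = 0.0151 (adjusted p = 0.538 and adjusted p = 0.537 with an estimated correlation). Beside them, 6 of the 11 neurons rich in glial markers were in 97Q RGFP109, and 97Q RGFP109 cell 9 of batch 2 had 14134 CPM of microglia markers and 1146 CPM of pan-neuronal markers. Proliferation markers had 9 of 12 lower and a median of -0.89. The proliferation list had a Benjamini-Hochberg adjusted p = 0.0259 by camera (adjusted p = 0.537 with an estimated correlation). Its member Rrm2 had 0.0898 CPM with RGFP109 and 12.3 CPM with vehicle. Oligodendrocyte markers had 8 of 8 lower and a median of -1.15. The oligodendrocyte list had a Benjamini-Hochberg adjusted p = 0.0424 by camera (adjusted p = 0.537 with an estimated correlation). Among its members Mbp had -1.79 (SE 1.57) and Bcas1 -5.68 (SE 2.64). Neurotrophin signalling was the 1 list that rose, with 15 of 17 higher and a median of 0.98 (0.17, 0.97 and 0.24 by batch). The neurotrophin list had a Benjamini-Hochberg adjusted p = 0.0135 by camera (adjusted p = 0.488 with an estimated correlation). Ntrk2 stood at 1.24 and Ntrk3 at 1.27.

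By single genes 0 passed in edgeR's quasi-likelihood test, with 375 at an unadjusted p under 0.05 (210 higher, 165 lower). DESeq2 called 110 (79 higher, 31 lower) and limma 0, with 798 at an unadjusted p under 0.05. The smallest p belonged to Stxbp2, a syntaxin-binding protein of vesicle release, at a log2FC of 1.90 (SE 0.440), from 43.6 ± 29.2 to 137 ± 80.3 CPM. Tef followed at 1.70 (SE 0.399), Kctd12 at 1.98 (SE 0.480), Ints3 at 1.68 (SE 0.409) and Zfp292 at 2.14 (SE 0.525). A single cell held 84.3%, 85.1% and 51.1% of the Kctd12 counts of 97Q RGFP109 in batches 1, 2 and 3. For Tef, a single cell held 99.4% of the counts of 97Q vehicle in batch 2. On the lower side were Spag7 at -1.16 (SE 0.304), the general transcription factor subunit Gtf2a2 at -1.37 (SE 0.376) and Eef1e1 at -1.21 (SE 0.339). With no gene filter, 1 of 37630 genes passed, Clec4n, a lectin of myeloid cells chosen after its values were seen (log2FC 12.2, SE 0.916, adjusted p = 0.0175 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of its 28510 counts, 99.96% came from 97Q RGFP109 cell 9.

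Of the 37 lists 9 passed (1 higher, 8 lower), with 0 past by an estimated correlation and 0 by fry. Of these 9 lists, 4 kept their call without batch 1, 4 without batch 2, 4 without batch 3, 1 with cells thinned to 50000 counts and 3 without the neurons rich in glial markers. The cholesterol list kept it in each of these settings (adjusted p up to 0.0468 by camera with Benjamini-Hochberg adjustment). Without batch 2 the median of the histone genes was 0.19. With the neurons rich in glial markers left out, 9 lists passed as well, but 5 were higher and 4 lower.

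The log2FC of RGFP109 in 97Q ran opposite to those of 97Q against 25Q, with a covariance across genes of -0.382 and a Pearson r of -0.45 over 15091 genes, which are not independent replicates. The covariance within batches 1, 2 and 3 was -0.609, -2.06 and -0.553. Groups of cells with labels shuffled within batches, which share cells between the contrasts in the same way, gave a mean of -0.446 (-0.655 to -0.320). With the 97Q vehicle cells divided between the contrasts the covariance was -0.0626 (-0.126 to 0.0625 in 100 draws), against -0.0240 (-0.164 to 0.131) in shuffled groups, so that no opposition beyond shared cells was detectable.

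The comparison of RGFP109 with vehicle in 25Q neurons asks for the effect of the inhibitor without the expanded tract. Gad1 had 2335 ± 1051 CPM with RGFP109 and 1739 ± 1212 CPM with vehicle (SD, n = 3), a log2FC of 0.57 (SE 0.238). Gad2 had 1308 ± 134 and 1304 ± 283 CPM, a log2FC of 0.01 (SE 0.236). Striatal projection neuron genes fell with 25 of 32 lower and a median log2FC of -1.10, which was -0.28 in batch 1, -2.83 in batch 2 and -0.16 in batch 3. The striatal list had a Benjamini-Hochberg adjusted p = 1.75e-05 by camera (adjusted p = 0.845 with an estimated correlation). Among them were the transcription factors Foxp1 at -1.54, Bcl11b at -1.32 and Ebf1 at -4.18, and Gng7 at -1.66. Interferon genes rose with 20 of 26 higher and a median of 0.97 (1.26, 1.07 and 0.01 by batch), and cholesterol synthesis genes with 22 of 25 higher and a median of 0.63 (-0.27, 0.65 and 0.90 by batch). Their Benjamini-Hochberg adjusted p by camera were 0.00309 and 0.0231 (adjusted p = 0.845 for both with an estimated correlation). Isg15 stood at 3.37 and Psmb8 at 2.64, from fewer than 2 CPM, and the cholesterol enzyme Dhcr7 at 0.99. Astrocyte markers had 15 of 22 higher and a median of 0.46, which was -0.81, 3.09 and -0.03 in batches 1, 2 and 3 (camera, Benjamini-Hochberg adjusted p = 0.0698).

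Histone deacetylase inhibitor response genes had 11 of 17 higher and a median log2FC of 0.09 (camera, Benjamini-Hochberg adjusted p = 0.576). The smallest p among single genes belonged to the transcriptional repressor Zbtb20, from 559 ± 224 to 106 ± 36.8 CPM (log2FC -2.32, SE 0.427). It was followed on the lower side by Twsg1 at -2.35 (SE 0.452), the Argonaute gene Ago3 at -3.24 (SE 0.742), Hddc2 at -1.62 (SE 0.407) and Lgi1 at -1.56 (SE 0.407). On the higher side were Fam168b at 2.06 (SE 0.508), the ceramide synthase Cers4 at 1.37 (SE 0.352), the calcium sensor Ncald at 2.13 (SE 0.545), and the phosphofructokinase Pfkp at 1.00 (SE 0.262). Arc stood at 6.05 (SE 1.59), and 60.0% of its counts under RGFP109 came from 1 cell. Calb2, an interneuron marker chosen after its values were seen, was higher when adjusted over the list alone (log2FC 5.75, adjusted p = 0.0321 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of its counts under RGFP109, 56.4% came from 1 cell, and it no longer passed without batch 1 or without batch 2 (adjusted p up to 0.221 over 16 settings). Htt had 0.59 (SE 0.604), Hdac1 1.24 (SE 0.869), Hdac3 0.34 (SE 0.284), Slc32a1 -0.20 (SE 0.973), Bdnf -1.98 (SE 4.10) and Ppp1r1b -2.19 (SE 1.66).

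By single genes 0 passed in edgeR's quasi-likelihood test, with 381 at an unadjusted p under 0.05 (169 higher, 212 lower). DESeq2 called 143 (61 higher, 82 lower) and limma 0, with 721 at an unadjusted p under 0.05. Of the 37 lists 3 passed, with 0 by an estimated correlation and 0 by fry. Without batch 2 all 3 lost their call, with a median of -0.22 for the striatal genes, 0.63 for the interferon genes and 0.39 for the cholesterol genes (camera, Benjamini-Hochberg adjusted p of 0.450, 0.127 and 0.127). The cholesterol list also lost it without batch 3 (0.433) and without the neurons rich in glial markers (0.177).

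The comparison of 97Q neurons under RGFP109 with 25Q neurons under vehicle asks what difference remained under treatment. Gad1 had a log2FC of -1.54 (SE 0.242) and Gad2 one of -1.29 (SE 0.239). Both were lower when adjusted over the list alone (0.00132 and 0.00210 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and neither when adjusted over all genes, where Gad1 had 0.554. Without the batch term the value of Gad1 over the list alone was 0.120, and with only the 2 groups in the fit that of Gad2 was 0.0585. The mean over batches of the log2 ratio of Gad1 was -1.60 with all cells and -2.71 without 97Q RGFP109 cell 10. Kit, chosen after its values were seen, had 14 counts in 97Q RGFP109 and was lower when adjusted over the list alone (0.0178 by edgeR's test with Benjamini-Hochberg adjustment). Without batch 1 or without batch 2 it did not pass (up to 0.139 over 15 settings). The smallest p belonged to Nnat, from 283 ± 162 to 46.4 ± 27.2 CPM (log2FC -2.62, SE 0.344, adjusted p = 0.392 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Pnck and Dbpht2 followed at -1.51 and -1.76. On the higher side were Tmem161b at 1.59, Efr3a at 1.67, and the synaptic vesicle genes Sv2a at 0.91 and Scamp5 at 1.18.

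Interferon genes rose with 25 of 26 higher (median log2FC 1.77, and 0.20, 2.00 and 1.47 by batch), proteasome genes with 36 of 46 (0.31, and 0.12, 0.64 and 0.22 by batch), oxidative stress genes with 24 of 30 (0.61, and -0.03, 1.39 and 0.31 by batch) and autophagy and lysosome genes with 40 of 51 (0.22, and 0.26, 0.16 and 0.14 by batch). Also higher were p53 targets with 23 of 32 (0.47) and astrocyte markers with 14 of 22 (0.48, and -0.37, 1.74 and 0.33 by batch). In this order, their Benjamini-Hochberg adjusted p by camera were 1.18e-06, 0.00316, 0.00316, 0.0284, 0.0482 and 0.0482 (adjusted p = 0.412 for the first 5 and adjusted p = 0.585 for astrocyte markers with an estimated correlation). Striatal projection neuron genes fell with 29 of 32 lower (-0.77, and -0.28, -1.47 and -1.05 by batch), and glutamate receptor genes with 31 of 40 (-0.79, and -0.13, -0.84 and -0.25 by batch). Also lower were immediate early genes with 17 of 23 (-0.92), histone genes with 18 of 22 (-0.57) and oxidative phosphorylation genes with 56 of 80 (-0.19). Their Benjamini-Hochberg adjusted p by camera were 2.68e-05, 9.71e-05, 0.0286, 0.0459 and 0.0482 (adjusted p = 0.412, 0.412, 0.418, 0.535 and 0.585 with an estimated correlation). Beside these lists, 6 of 26 neurons of 97Q RGFP109 and 3 of 29 of 25Q vehicle were rich in glial markers.

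Of the 37 lists 11 passed (6 higher, 5 lower), with 0 by an estimated correlation and 0 by fry. Without the 11 neurons rich in glial markers only 1 of the 11 passed, autophagy and lysosome (median 0.29, adjusted p = 0.0251 by camera with Benjamini-Hochberg adjustment). The medians of the interferon and striatal genes were then 0.37 and -0.63 (adjusted p = 0.538 and 0.0656) and that of astrocyte markers -0.59. The astrocyte list was part of the criterion by which those neurons were left out, which favours its fall. Of the 11 lists, 8 kept their call without batch 1, 6 without batch 2 and 6 without batch 3. The striatal, glutamate receptor and interferon genes kept theirs each time. By single genes 0 passed in edgeR's quasi-likelihood test, with 503 at an unadjusted p under 0.05 (243 higher, 260 lower). DESeq2 called 188 (76 higher, 112 lower) and limma 0, with 945 at an unadjusted p under 0.05. With no gene filter Clec4n alone passed (adjusted p = 0.0126 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from the same single cell.

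The interaction tests whether RGFP109 acted differently in 97Q and in 25Q neurons. Striatal projection neuron genes had a higher drug effect in 97Q, with 26 of 32 higher and a median log2 difference of 1.90 (0.83, 3.41 and -0.36 by batch). The striatal list had a Benjamini-Hochberg adjusted p = 3.42e-06 by camera (adjusted p = 0.548 with an estimated correlation). Cholesterol synthesis genes had a lower one, with 22 of 25 lower and a median of -1.13 (-0.45, -2.33 and -0.95 by batch). The cholesterol list had a Benjamini-Hochberg adjusted p = 5.53e-06 by camera (adjusted p = 0.548 with an estimated correlation). Proliferation markers (median -2.42), proteasome genes (-0.33), pan-neuronal markers (-0.41), oligodendrocyte markers (-2.10) and histone genes (-0.77) also had a lower drug effect in 97Q. By batch, their medians were -0.85, -1.075 and -2.19 for proliferation, -0.41, -0.57 and -0.27 for proteasome, -0.68, -1.33 and 0.245 for pan-neuronal, -0.69, -4.21 and -0.86 for oligodendrocyte and 0.11, -1.75 and -0.075 for histone genes. In the order named first, the Benjamini-Hochberg adjusted p by camera were 0.00253, 0.00601, 0.0226, 0.0305 and 0.0425 (adjusted p = 0.548 for the first 4 and adjusted p = 0.645 for histone genes with an estimated correlation). Microglia markers had 5 of 7 higher and a median of 2.68 (camera, Benjamini-Hochberg adjusted p = 0.161). Among single genes, Kctd12 had a log2 difference of 3.32, Tef 2.47, Zbtb20 2.37, Twsg1 2.36 and Ago3 3.69. For Kctd12, a single cell held 51.1 to 85.1% of the counts of 97Q RGFP109 in each batch. On the lower side Sccpdh had -1.67, Fam169a -3.26, Pfkp -1.24, Nrep -2.87 and H3f3b -1.29. Rrm2, chosen after its values were seen, had -11.75 and passed when adjusted over the list alone (0.0232 by edgeR's test with Benjamini-Hochberg adjustment) at 11 counts in 97Q RGFP109. It did not pass without batch 1, without batch 3 or without the neurons rich in glial markers (up to 0.388 over 13 settings).

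Of the 37 lists 7 passed, with 0 by an estimated correlation and 0 by fry. Without batch 2 the striatal list had a median of 0.48 and a Benjamini-Hochberg adjusted p = 0.0939 by camera, while the cholesterol list passed without each batch (adjusted p up to 0.00283). Of the 7 lists, 3 kept their call without batch 2, namely cholesterol, proteasome and proliferation, and 4 each without batch 1 and without batch 3. By single genes 0 passed in edgeR's quasi-likelihood test, with 393 at an unadjusted p under 0.05 (239 higher, 154 lower). DESeq2 called 70 (56 higher, 14 lower) and limma 0, with 734 at an unadjusted p under 0.05.

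Empty vector neurons, the control without a transgene, were compared with 25Q neurons of the same batch. Gad1 had 2808 CPM (2792 to 2824) in empty vector and 3149 CPM (3136 to 3162) in 25Q neurons, and Gad2 had 1550 CPM (1538 to 1562) and 1554 CPM (1545 to 1564). Striatal projection neuron genes were lower in empty vector neurons, with 25 of 32 lower and a median log2 ratio of -0.85 (random lists -0.35 to 0.27), and dopamine and cAMP signalling genes had a median of -0.53. By cells, the striatal list took 2366.5 CPM in the median empty vector cell and 2457 CPM in the median 25Q cell. Interferon genes had 21 of 26 lower and a median of -0.41, at percentile 5.7 of random lists. The highest ratios under the naming rule belonged to Tmem151a (237 CPM, 232 to 242, against 12.4 CPM, 11.6 to 13.3), Sephs2, Fam210b, Calb1 and Tpgs1, with log2 ratios of 4.15 to 3.80. The lowest belonged to Pomt1 (0.935 CPM, 0.668 to 1.27, against 41.8 CPM, 40.2 to 43.3), Bbs9, Plce1, Cep57l1 and Tfdp2, with log2 ratios of -4.47 to -3.51. Across genes the Pearson r of log2(CPM + 1) was 0.879, where genes are not independent replicates.

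Astrocytes of batch 3 served as a background for neuronal transcripts. Their astrocyte marker list took 46820 CPM, against 2218 CPM in the 64 neurons of that batch, and their pan-neuronal list 933 CPM, against 11614 CPM. Gfap had 1601 CPM (1593 to 1608) in astrocytes and 13.9 CPM in neurons, Aqp4 1116 and 28.9 CPM, and Slc1a3 1096 and 45.2 CPM. The other way round, the astrocyte marker Slc1a2 had 30.8 CPM in astrocytes and 58.8 CPM in neurons. Gad1 had 0.538 CPM (0.403 to 0.704) in astrocytes and 2173 CPM in neurons, Gad2 0.223 and 1091 CPM, and Snap25 0.538 and 3074 CPM.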

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

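The tests of explanations for the 3 patterns weighed here, including the single cells and the neurons rich in glial markers left out, and the counts over other splits of the sums were chosen only after the results were seen.

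The drug effect differed between 97Q and 25Q neurons for 7 lists by the test of the difference itself (camera with the preset correlation, 0 lists with an estimated correlation). The median log2 difference, 97Q minus 25Q, was 1.90 for striatal projection neuron genes, -1.13 for cholesterol synthesis, -0.331 for proteasome genes, -0.766 for histone genes, -0.408 for pan-neuronal markers, -2.10 for oligodendrocyte markers and -2.42 for proliferation markers. Without batch 2, 3 of the 7 lists kept their call, the striatal median was 0.482 and no longer passed, and the histone median was 0.094.

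Among the 9 empty vector neurons, 21 values were searched for a cell far from the others, and 7 values had such a cell. By chance such a search picks about 1 in 20 values if they are spread normally and are independent. The CPM were not transformed, and in all 7 values the outlying cell was the highest. The 7 can therefore not be set against that rate. Cell 8 had 44.7 CPM of Slc32a1, 5616 CPM of striatal projection neuron genes and 5069 CPM of striatal interneuron markers. Cell 3 had 193.6 CPM of Ppp1r1b. Cell 1 had 7698 CPM of astrocyte markers, 140.8 CPM of fibroblast and meningeal markers and 1478 CPM of proliferation markers.

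Gad1 and Gad2 were lower in 97Q than in 25Q neurons under vehicle, with a log2FC of -1.83 and -1.42. Dilution by RNA of other cells would have lowered all neuronal transcripts alike, but the median log2FC of pan-neuronal markers was 0.446. A single cell did not carry the difference, since leaving out each of the 55 cells in turn left log2 ratios of at most -1.14, and more neurons without GABA synthesis among the 97Q cells are argued against by the 96.2% of 97Q neurons with at least 100 CPM of Gad2. A lower transcript level per neuron with the expanded tract may account for the pattern and stays open as a hypothesis found and tested on the same data. Open and untested as well are differences between cultures, which the labels do not name, and a choice of neurons for recording that differed between groups.

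The log2FC of RGFP109 in 97Q ran opposite to those of 97Q against 25Q, with a covariance of -0.382. A candidate explanation is that both contrasts hold the 97Q vehicle cells with opposite sign. With these cells divided between the contrasts the covariance was -0.0626, inside the range of shuffled groups (-0.164 to 0.131), and shuffled groups that share the cells gave -0.446. A reversal of part of the 97Q effect by the drug, smaller than this design resolves, stays open. No other technical explanation was tested.

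Striatal projection neuron genes were lower than in 25Q vehicle neurons in 97Q (-1.52), 25Q RGFP109 (-1.10) and 97Q RGFP109 neurons (-0.77), comparisons that all hold the same 25Q vehicle cells. Those cells may carry part of the pattern, since empty vector neurons of batch 3 also lay below them, with a median log2 ratio of -0.847. By cells the groups were close, with 2366.5 CPM of the list in the median empty vector cell. The median 25Q vehicle cell had 2457 CPM, and the highest 10991 CPM. In the same batch 25Q RGFP109 neurons did not lie below 25Q vehicle neurons by the summed list, with 3378 against 3273 CPM. By cells they did, with 2140 CPM in the median 25Q RGFP109 cell, and the highest held 16443 CPM. The measures differ and rest partly on single cells, so batch 3 does not decide the question. For the 97Q part, the median was -1.42 without the neurons rich in glial markers. That setting cannot decide about RNA of glial cells. It took only cell 7 out of the 97Q vehicle neurons, and cells 5, 6 and 10 out of the 25Q vehicle neurons. For the 25Q RGFP109 part, batch 2 is a candidate source, because the median without it was -0.224 and no longer passed, whereas 97Q against 25Q without it stood at -1.13 and passed. An effect of the expanded tract on these genes beyond the shared cells stays open, as does an effect of carrying the 25Q construct, which cannot be separated here from the sampling of those cells.

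For each contrast the 6 sums of 2 groups form 10 splits (for the interaction those of 97Q vehicle and 97Q RGFP109, with the 25Q sums left as they are), too few for a share under 0.05, so chance was not tested to that level. Gene lists past the threshold numbered 16 in 97Q against 25Q and at most 16 in the other splits (2 of 10 splits gave as many), 9 and at most 4 for RGFP109 in 97Q (1 of 10), 3 and at most 5 for RGFP109 in 25Q (7 of 10), 11 and at most 9 for 97Q RGFP109 against 25Q (1 of 10), and 7 and at most 6 for the interaction (1 of 10). The other split with 16 lists put 25Q batch 1, 97Q batch 1 and 97Q batch 2 against the remaining 3 sums. It has both sums of batch 1 on one side and both of batch 3 on the other, but another split with this layout gave 5 lists, so the layout alone does not account for the 16, and the cause was not tested. The 3 splits that only exchange the groups within a batch gave 6, 3 and 9 lists. Single genes past the threshold numbered 0 in all 10 splits of each contrast. Genes at an unadjusted p under 0.05 numbered 597, 375, 381, 503 and 393 in the 5 contrasts in this order and at most 728, 667, 601, 642 and 595 in the other splits, with as many in 3, 6, 4, 3 and 6 of 10 splits. Splits that only exchange groups within a batch gave 330, 279 and 200 for 97Q against 25Q, and 471, 419 and 268 for RGFP109 in 97Q. They gave 278, 305 and 274 for RGFP109 in 25Q, and 304, 330 and 302 for 97Q RGFP109 against 25Q. For the interaction they gave 443, 431 and 358. Such splits thus reached the real number only for RGFP109 in 97Q and for the interaction.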

How the results depend on the processing

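Cells thinned to 900000 counts, the neurons rich in glial markers left out and single cells left out were chosen only after the data were seen. Apart from counts over whole comparisons, the direction held but the threshold was no longer passed for 214 values under settings fixed beforehand and 32 under those chosen later. The sign was the other one for 27 and 3 values of named genes, none of them past the threshold, among them Gad1 and Gad2 for RGFP109 in 97Q by limma (-0.16 and -0.55). A further 50 newly passed, all of them named genes by DESeq2 (Gad1 and Gad2 in 97Q against 25Q among them), which called 213 genes in 97Q against 25Q, 110 for RGFP109 in 97Q, 143 for RGFP109 in 25Q, 188 for 97Q RGFP109 against 25Q and 70 for the interaction. In simulated data DESeq2 called 186 of 14891 unchanged genes and edgeR 0, which bears on those counts. With no gene filter 1 gene passed for RGFP109 in 97Q and 1 for 97Q RGFP109 against 25Q, both times Clec4n from a single cell, and 0 with filterByExpr alone.

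Gene lists past the threshold depended most on the correlation between genes: 0 passed in each of the 5 contrasts by camera with an estimated correlation and 0 by fry, against 16, 9, 3, 11 and 7 with the preset one. In simulated data the estimated correlation did call the lowered list, but genes were drawn independently there. That call does not bear on lists whose genes vary together. With cells thinned to 50000 counts 1 list passed for RGFP109 in 97Q and 2 for the interaction, where fewer lists (32) held enough genes. For 97Q RGFP109 against 25Q, 7 passed with the astrocyte covariate, 7 with cells thinned to 900000 counts and 1 without the neurons rich in glial markers, and the cause was not tested further. With each batch (the replicate) left out in turn, 4 to 5 lists passed for RGFP109 in 97Q, 1 to 5 for RGFP109 in 25Q, 7 to 10 for 97Q RGFP109 against 25Q and 4 to 6 for the interaction, each from fewer residual degrees of freedom (3). With no replicate block, that is without the batch term that pairs the sums, 15, 7, 3, 8 and 5 lists passed and 0 genes.

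The direction by camera turned for 3 lists, and the cause was not tested. Without batch 2 the medians of 2 further results crossed 0 (0.035 for GABA receptor genes in 97Q against 25Q, 0.094 for histone genes in the interaction). The median of histone genes for RGFP109 in 97Q ran from -0.949 to 0.193 with each batch left out. For 97Q RGFP109 against 25Q, that of astrocyte markers ran from -0.13 to 1.008 and was -0.594 without the neurons rich in glial markers, and oxidative phosphorylation genes, which camera then placed higher, had a median of -0.046 without those neurons. The fall of astrocyte markers was favoured by the choice of those neurons, since the astrocyte list was part of the criterion. The covariance of the drug effect in 97Q and the 97Q effect was -0.0626 with divided cells, which removes the shared cells by construction, -0.559 with cells thinned to 50000 counts, and -0.718 to -0.325 with each batch left out. The log2 ratio of Gad1 in empty vector over 25Q neurons was -0.165, and -0.178 thinned. Keeping all cells and a minimum of 3000 genes removed no cell, so these settings test nothing. Depth per cell did not limit Gad1 or Gad2, whereas 97Q against 25Q rests on 3 batches, and batch 2 on 15 neurons.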

Other observations

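No test was run on the values given here, and they were chosen only after the data were seen.

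Astrocytes of batch 3 were rich in further lists. Endothelial and mural markers took 5163 CPM in astrocytes (median cell 882 CPM, 296 to 26401 CPM) and 166 CPM in the neurons of that batch, oligodendrocyte markers 745 and 152 CPM, and fibroblast and meningeal markers 376 and 115 CPM. Single members of the oligodendrocyte list went the other way, with 1 count of Mbp in astrocytes against 45.5 CPM in neurons and 0 counts of Pdgfra against 2.28 CPM. The astrocyte list took between 29521 and 98387 CPM in single astrocytes. Clu had 7475 CPM (7458 to 7492) and Aldh1l1 608 CPM (603 to 613), while C1qa and Col1a1 had 0 counts, which allows up to 0.0375 CPM each. Hdac3 had 201 CPM (198 to 204) and Hdac1 52.2 CPM (50.8 to 53.6) in astrocytes.

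In empty vector neurons, proliferation markers had a median log2 ratio over 25Q of 1.94 and fibroblast markers one of -1.43, axonal transport motors 0.21 and genes of synaptic vesicle endocytosis 0.22, each outside the central range of random lists. Cell 1 held 1478 CPM of proliferation markers and the next cell 132 CPM, and the median cell had 56.5 CPM, against 79.1 CPM in 25Q neurons of batch 3. Of 37 lists, 3 lay below it and 3 above it. GABA synthesis genes had a median of 0.08, at percentile 79.6. Nnat had 540 CPM (533 to 547) against 279 CPM (275 to 283), and Htt 32.6 CPM (30.9 to 34.3) against 14.3 CPM (13.4 to 15.2). Of the Nnat counts, 48.3% came from 1 cell in empty vector and 38.7% from 1 cell in 25Q neurons. By cells Nnat was not higher, with 191.9 CPM in the median empty vector cell and 212.4 CPM in the median 25Q cell. For Htt, 47.7% of the empty vector counts came from 1 cell, and with cells thinned to 50000 counts the log2 ratio was 0.095, against 1.14 with all counts. Bdnf had 1 count in empty vector and 977 in 25Q neurons, which is 0.0234 CPM (0.000592 to 0.130) against 14.2 CPM (13.3 to 15.1). Of the 977 counts, 54.4% came from 1 cell.

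Transcripts of Xist exceeded those of Y-linked genes in 0 of 34 neurons of batch 1, 0 of 15 of batch 2 and 29 of 64 (45.3%) of batch 3, and in 7 of 14 astrocytes. In batch 3 this held for 7 of 15 neurons of 25Q vehicle, 5 of 15 of 97Q vehicle, 6 of 11 of 25Q RGFP109, 5 of 14 of 97Q RGFP109 and 6 of 9 with the empty vector.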
